A study of Drosophila melanogaster with 12 samples.

How the data were processed

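Poly(A)-selected mRNA from Drosophila melanogaster ovaries was sequenced in 12 libraries, all labelled as dissected 1 to 3 days after eclosion. The libraries form 6 sets of 2: germline knockdowns (GKD) of SETDB1, wde and Nup154, a pair of young controls whose titles name NGVP16, a pair of young controls whose titles name virgin flies, and a pair labelled adult control. Per the labels' protocols, RNA was extracted with TRIzol or phenol-chloroform, treated with DNase, selected with poly(A) beads and made into libraries with a directional kit. Nothing in the labels says that the replicates came from separate flies or crosses, so p-values measure only the spread between these libraries, which may be technical.

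The deposited files hold raw whole-number counts per FlyBase gene identifier, 1 file per library, with no normalization. Per the submitters' processing notes, the tools were HISAT2 2.1.0, featureCounts 1.4.6 and DESeq2 1.24.0, with the genome build dm6. The role of each tool, the annotation release and the strand setting used for the counts are not given in the sources used here. Gene symbols and positions came from the Ensembl release 115 annotation of BDGP6, whose coordinates are those of dm6, and 16647 of the 17023 identifiers were named. The other 376 kept their identifiers, held 5.95% to 6.94% of the counts in the knockdown and young control libraries, and are not named in the text.

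Total counts per library were 14433500 and 9937877 for SETDB1 GKD, 10242055 and 10365789 for wde GKD, and 11508672 and 11813990 for Nup154 GKD. They were 8155977 and 11609262 for the NGVP16 pair, 20162235 and 7351948 for the virgin pair, and 471770 and 682565 for the adult pair. No pair of replicates differed by as little as sampling noise. The median over genes of the squared replicate difference, over that of sampling noise, was 2.06 in the adult pair, 5.42 in Nup154 GKD and 56.6 in the NGVP16 pair. Intervals and floors given for low counts cover counting error only, since the reads carry no molecular identifiers that would mark independent molecules.

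Genes with low counts were removed with filterByExpr, which left 10790, and libraries were scaled by TMM. The quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) was fitted to all 12 libraries with 1 mean per set, in R 4.3.3. This gave 6 residual degrees of freedom and a common biological coefficient of variation of 0.381. All adjusted p-values of genes are from this test with Benjamini-Hochberg adjustment, at a threshold of 0.05, unless another tool is named. Log2 fold changes are given with a standard error (SE) worked back from the test, as their absolute value over the square root of F. It is approximate, also where a set is near 0 counts. Levels are CPM (counts scaled to the library size after TMM) with the SD over n = 2 libraries. Where a set held 0 counts of a gene, its fold was bounded against a floor of 3 counts over the set. Where it held 1 to 3 counts, the ratio of CPM is given with an exact interval.

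The knockdowns were compared with the NGVP16 pair and one another, the adult pair with the virgin pair, and the virgin with the NGVP16 pair. The titles of the knockdown and NGVP16 libraries share 1 running number, which other titles lack, so the NGVP16 pair was the control. Test, control, gene lists and the rule for naming genes were fixed before the data were examined. The rule names egg (the gene of SETDB1), wde and Nup154 in every comparison. It adds RpS19b, blanks, Phf7 and bam for knockdowns, and all nucleoporin genes. Between knockdowns, egg, wde, Nup154 and bam are not given. For each knockdown it takes the 10 largest rises and 10 largest falls among genes past the test with at least 10 CPM in the higher set and no overlap of the sets. For other comparisons it takes 5 of each. From each gene list it takes up to 4 members. Symbols that are only annotation numbers and noncoding RNAs were left out.

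Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, 2-sided and adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The lists covered nucleoporins, nuclear transport factors, nuclear lamina and envelope, and H3K9 methylation and heterochromatin factors. They also covered germ cell and early oogenesis genes, testis-enriched genes, meiosis, oocyte and maternal mRNAs, the piRNA pathway, eggshell, yolk, follicle cells, germarium niche cells and ecdysone response. Lists for other tissues and states were muscle sheath, fat body, hemocytes, gut, reproductive tract, neurons, cell death, heat shock, immunity, Polycomb group, Hox genes, pericentric heterochromatin genes, Y-linked genes, cytoplasmic ribosomal proteins and the genes of each chromosome arm. RpS19b, blanks and the nucleoporin list were included because the study is known to have examined them, so they are not independent evidence of a direction. The overlap of knockdowns was compared with 20 simulations of unchanged groups that shared the NGVP16 controls.

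Besides the settings above, 36 others were run. Of these, 31 were planned: other scalings (DESeq2 size factors, upper quartile, ribosomal protein counts), no filter or a filter at 5 CPM, DESeq2 1.42.0 and limma voom as tests, fewer libraries, other young controls, a replicate block, removal of eggshell and yolk genes, a 2-fold limit, other list tests, split controls and each library left out. The other 5 were added after the data had been seen: without the adult pair, without that pair and NGVP16 control 1, 2 ways of removing a trend with gene length, and lists without the 3 targeted genes. Counts of genes past the test from all 12 libraries, from 10 without the adult pair and from 8 were seen before the text was written, and the fit to 12 stayed the main one because it had been fixed. In simulated data of SETDB1 GKD against control, 200 of 10400 genes were changed. The test found 2% of 2-fold and 47% of 4-fold changes, with 0 false calls among 50. More genes were called in the data, so the power there is unknown. Transposons, small RNAs and splicing were not analysed here.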

Results

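Gene expression in Drosophila ovaries was measured by poly(A) mRNA sequencing in 12 libraries, in 6 sets of n = 2. By their labels, 3 sets carried a germline knockdown (GKD) of SETDB1, wde or Nup154. SETDB1 is the H3K9 methyltransferase encoded by egg, Wde is its cofactor, and Nup154 is a protein of the nuclear pore. The series uses the Nup154 knockdown as a control for the developmental defect that the knockdowns share. The other sets were the NGVP16 young controls, the virgin young controls and the adult controls. Total counts per library ran from 471770 in adult control 1 to 20162235 in virgin control 1. Log2 fold changes are given ± SE, and levels in CPM ± SD over n = 2 libraries.

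The knockdown ovaries held more muscle RNA and less eggshell RNA than the young controls. Muscle sheath genes took 3.1% ± 0.378 of the counts in SETDB1 GKD, 2.75% ± 0.136 in wde GKD and 2.72% ± 0.0438 in Nup154 GKD, against 0.494% ± 0.0568 in the NGVP16 pair and 0.367% ± 0.00721 in the virgin pair (SD, n = 2). Eggshell genes, which code for the vitelline membrane and chorion, took 0.0181% ± 0.00241, 0.0964% ± 0.116 and 0.068% ± 0.00502 in the 3 knockdowns, against 0.583% ± 0.275 and 0.839% ± 0.222 in the young controls. Without the adult pair, the first principal component held 56.6% of the variance and placed the knockdowns at -25.9 to -108 and the young controls at 68.7 to 127. NGVP16 control 1 stood apart from NGVP16 control 2. Ribosomal protein genes took 24.1% of its counts against 9.5%, and the difference of the 2 libraries followed exon length across 5320 genes (Spearman's rho = -0.769, genes not being independent replicates). The same rho was -0.585 in the virgin pair, 0.271 in SETDB1 GKD, 0.165 in wde GKD and 0.0468 in Nup154 GKD. Scaling to the ribosomal protein genes moved the median log2 fold change of all genes to 0.455, 0.749 and 0.299 in the 3 knockdowns, and DESeq2 size factors moved it to 0.145 in SETDB1 GKD and 0.172 in wde GKD. Between the knockdowns, ribosomal protein scaling gave medians of -0.291 for SETDB1 GKD against wde GKD, 0.116 for SETDB1 GKD against Nup154 GKD and 0.4 for wde GKD against Nup154 GKD, and upper quartile scaling gave 0.114 for SETDB1 GKD against Nup154 GKD.

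Of the 3 targeted genes, Nup154 alone passed the test as lower in its own knockdown. Nup154 (FBgn0021761, chromosome 2L, 11004820 to 11010921) was at 70.0 CPM ± 3.17 in Nup154 GKD against 189 ± 61.2 in the NGVP16 pair, a log2 fold change of -1.43 ± 0.33 (adjusted p = 0.00695). It was also lower in wde GKD, at 81.0 CPM ± 23.9 (-1.22 ± 0.33, adjusted p = 0.0157). In SETDB1 GKD it was at -0.97 ± 0.33 (adjusted p = 0.0542, range over the settings other than the 2-fold limit 0.0013 to 0.579). There it was at -1.21 without NGVP16 control 1, -0.58 without control 2 and -1.43 against the virgin pair (adjusted p = 0.00748). egg (FBgn0086908, chromosome 2R, 24775534 to 24779901) was at 33.5 CPM ± 5.84 in the libraries labelled SETDB1 GKD against 54.1 ± 27.4, or -0.70 ± 0.35 (adjusted p = 0.178). Its NGVP16 libraries differed, at 34.7 and 73.4 CPM. Without NGVP16 control 1 the change of egg was -1.08 and without control 2 it was -0.04. Against the virgin pair, at 70.7 CPM ± 8.24, it was -1.08 (adjusted p = 0.039). Over the settings with at least 2 libraries per set, the 2-fold limit aside, its adjusted p ran from 0.00404 to 0.752. wde (FBgn0027499, chromosome 2R, 10800420 to 10808938) was at 74.6 CPM ± 12.5 in the libraries labelled wde GKD against 95.8 ± 73.9, or -0.36 ± 0.44 (adjusted p = 0.54). Against the virgin pair it was -0.29 (0.613). Its level was 91.1 CPM ± 7.26 in the virgin pair and 204 CPM ± 17.6 in SETDB1 GKD (1.09 ± 0.44 against NGVP16, adjusted p = 0.101, range over the settings 0.000227 to 0.386), where the change was 0.52 without NGVP16 control 1 (adjusted p = 0.151) and 2.24 without control 2 (0.000227). wde turned without NGVP16 control 2, to 0.78 in wde GKD and 0.9 in Nup154 GKD, and was at -0.87 and -0.86 without control 1. The Nup154 call ended without Nup154 GKD 1 (adjusted p = 0.0594) or 2 (0.0727, range over the settings 2.43e-05 to 0.209), and its call in wde GKD ended without wde GKD 1 (0.156, range 0.000441 to 0.565). egg and Nup154 overlap genes on the opposite strand.

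**Figure D1:**
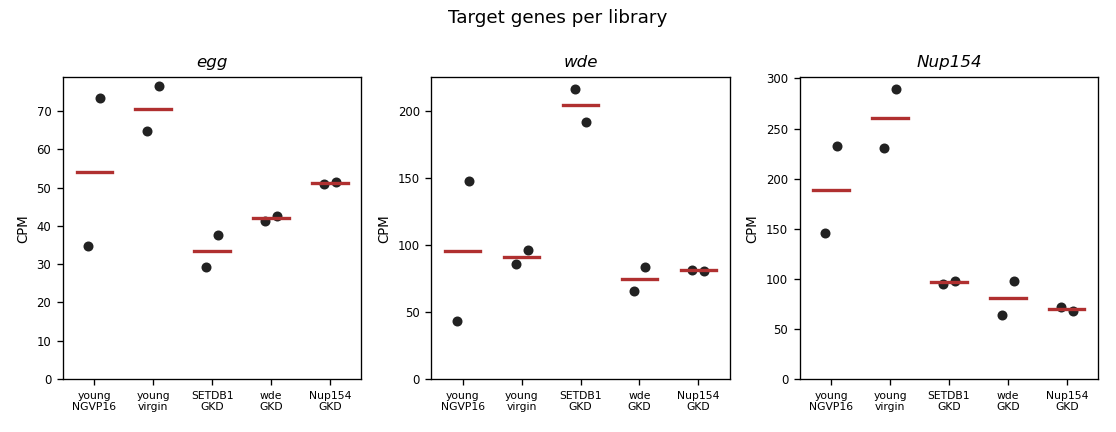
Levels of egg, wde and Nup154 in CPM (vertical axis) for each library, by set, with the mean as a line. Nup154 sits near 70.0 CPM in its knockdown against 189 in the NGVP16 pair, while the NGVP16 libraries lie at 34.7 and 73.4 CPM for egg.

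The libraries labelled SETDB1 GKD were compared with the NGVP16 pair to find which genes differ in them. RpS19b, a germline ribosomal protein gene of early oogenesis (FBgn0039129, chromosome 3R, 23932729 to 23933530), rose to 58.5 CPM ± 4.71 from 3.41 ± 0.811 (4.11 ± 0.45, adjusted p = 0.000375). blanks (FBgn0035608, chromosome 3L, 5497523 to 5498958), which encodes a protein that binds double-stranded RNA in the testis, rose to 134 CPM ± 47.6 from 3.93 ± 4.26 (5.14 ± 0.92, adjusted p = 0.00518). Phf7 (FBgn0031091, chromosome X, 20160355 to 20165830), a chromatin reader of the male germline, rose to 88.9 CPM ± 17.0 from 35.2 (1.34 ± 0.34, adjusted p = 0.0162; 0.109 without SETDB1 GKD 1, range over the settings 1.21e-05 to 0.109). bam (FBgn0000158, chromosome 3R, 25243039 to 25245109), the switch for germline differentiation, was at -1.45 ± 0.54 (adjusted p = 0.0804). RpL22-like, the paralog of RpL22, rose to 155 CPM ± 44.3 from 0.209 (9.24 ± 0.74, adjusted p = 0.00017), and gNacalpha, a nascent polypeptide-associated subunit, rose to 190 CPM ± 6.49 from 1.30 (7.28 ± 0.64, adjusted p = 0.00023). eIF3f2, the second copy of a translation initiation subunit, was at 23.9 CPM ± 9.26 and at 0 counts in the control, at least 167-fold higher. eIF4E3 was higher by a ratio of 250 (interval 44.6 to 9916), and Ugt37B1, a UDP-glycosyltransferase, was at least 78.8-fold higher. RpL37-2 (7.77 ± 0.92) and ATPsynepsilonL (7.65 ± 0.88) rose too, and without NGVP16 control 2 their only control held 0 counts (fitted values 11.79 and 11.98, no bound). The calls of tobi and Jon74E, digestive enzymes, ended without SETDB1 GKD 1. Both also ended without NGVP16 control 1 or 2, so they cannot be laid to 1 library.

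The largest falls in SETDB1 GKD included eggshell genes. APC7, a subunit of the anaphase-promoting complex, fell to 1.67 CPM from 140 ± 17.7 (-6.34 ± 0.46, adjusted p = 8.21e-05). The chorion genes Cp7Fc (-8.02 ± 0.89), Cp36 (-7.63 ± 0.88) and Cp38 (-7.36 ± 1.12), the vitelline membrane gene Vm26Ac (-7.42 ± 0.80) and the odorant-binding protein gene Obp19c (-7.68 ± 0.85) fell as well. Of the 24 eggshell genes tested, 20 fell and 0 rose (22 fell adjusted over the list alone), with a median of -5.35 (camera adjusted p = 2.35e-10, and adjusted p = 0.153 with an estimated correlation), in libraries whose eggshell share was 0.0181%. Of 33 oocyte and maternal mRNAs, 26 fell and 0 rose (26 adjusted over the list alone), with a median of -2.61 (adjusted p = 5.31e-14, and adjusted p = 0.153 with an estimated correlation). Among them dhd, a thioredoxin of the egg, fell to 53.5 CPM ± 23.3 from 1623 ± 751 (-4.92 ± 0.61), and exu, which carries bicoid mRNA, fell by 4.71 ± 0.36. Of 5 yolk genes 3 fell (3 adjusted over the list alone), such as the yolk receptor yl (-4.63 ± 0.57) and the yolk protein gene Yp2 (-3.20 ± 0.60). The list median was -2.03 (adjusted p = 0.00394, and adjusted p = 0.271 with an estimated correlation). Of 33 piRNA pathway genes 8 fell and 1 rose (9 and 1 adjusted over the list alone): Boot fell by 2.41 ± 0.35 and fs(1)Yb, which acts in somatic cells, rose by 1.63 ± 0.30. Over the list the median was -0.36 (adjusted p = 0.0186, and adjusted p = 0.862 with an estimated correlation). The median of that list turned to 0.09 with ribosomal protein scaling, and its adjusted p was 0.0551 without SETDB1 GKD 1 and 0.562 without NGVP16 control 2 (range over the settings 0.000989 to 0.862). The calls of 4 other eggshell genes among the largest falls ended in single left-out fits: Vm34Ca, Vm32E, Vml and Vm26Aa without NGVP16 control 1 (adjusted p = 0.0711, 0.0516, 0.0643 and 0.061), the first 3 without SETDB1 GKD 1 (0.0535, 0.0579 and 0.0697), and Vm34Ca, Vml and Vm26Aa without SETDB1 GKD 2 (0.0589, 0.0638 and 0.0503), with ranges over the settings that reach down to 3.36e-08, 3e-04, 2.07e-08 and 5e-09 and up to 0.0711, 0.0579, 0.0887 and 0.0876.

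The SETDB1 GKD libraries held more muscle RNA (3.1% against 0.494%). Of 24 muscle sheath genes 18 rose and 0 fell (21 rose adjusted over the list alone), with a median of 2.56 (adjusted p = 6.12e-14, and adjusted p = 0.14 with an estimated correlation). Mhc, the myosin heavy chain, rose to 3710 CPM ± 130 from 494 ± 313, and Act87E, an actin, rose by 3.54 ± 0.38. Of 15 germarium niche genes 10 rose (10 adjusted over the list alone), among them Con (4.08 ± 0.53) and the signal hh (3.86 ± 0.73). As a list these had a median of 1.89 (adjusted p = 3.5e-06, and adjusted p = 0.153 with an estimated correlation), and 3.29 without NGVP16 control 2. Of 20 follicle cell genes 7 rose (8 adjusted over the list alone), such as the adhesion protein Fas3, at 596 CPM ± 17.5 from 61.6 ± 17.7, and the transcription factor kay (2.44 ± 0.35). Together these had a median of 1.08 (adjusted p = 0.00124, and adjusted p = 0.604 with an estimated correlation), and 0.51 without NGVP16 control 1. Of 12 hemocyte genes 10 rose (11 adjusted over the list alone), such as the peroxidasin Pxn, at 647 CPM ± 110 from 22.2 ± 14.1. For the list the median was 2.74 (adjusted p = 3.85e-08, and adjusted p = 0.153 with an estimated correlation). Of 9 genes of the spermatheca, oviduct and accessory tract 5 rose (5 adjusted over the list alone, median 2.52, adjusted p = 0.00394, and adjusted p = 0.153 with an estimated correlation), such as the octopamine receptor Octbeta2R (2.84 ± 0.36). Without NGVP16 control 2 the adjusted p of this list was 0.0666 (range over the settings 0.000314 to 0.153). Of 21 neuronal genes 5 rose and 1 fell (10 and 2 adjusted over the list alone). The median over the list was 1.45 (adjusted p = 0.012, and adjusted p = 0.604 with an estimated correlation). The neuronal call ended without NGVP16 control 1 (0.182, median 1) or with ribosomal protein scaling (0.0573), and its median was 2.92 without control 2, over a range of adjusted p from 0.000257 to 0.604.

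Few chromatin and germline lists here passed in SETDB1 GKD. Of the 90 genes tested on chromosome 4, which is largely heterochromatic, 19 rose and 1 fell (19 and 1 adjusted over the list alone). Across the list the median was 0.54 (adjusted p = 0.000691, and adjusted p = 0.604 with an estimated correlation), 0.32 without NGVP16 control 1 and 1.43 without control 2. Of 21 H3K9 methylation and heterochromatin factors 1 rose and 2 fell (1 and 1 adjusted over the list alone), where HP6, a heterochromatin protein copy that overlaps dpy on the same strand, rose by 5.42 ± 1.10. The list median was -0.39 (adjusted p = 0.321). Of 18 germ cell genes 5 rose and 2 fell (6 and 3 adjusted over the list alone), with the cyclin CycA at -2.08 ± 0.40 and at -1.38 without NGVP16 control 2. Over the list the median was 0.59 (adjusted p = 0.35). Of 20 testis-enriched genes 2 rose and 1 fell (1 and 1 adjusted over the list alone). As a list these had a median of 1.48 (adjusted p = 0.418). Of 24 meiosis genes 4 rose and 4 fell (4 and 4 adjusted over the list alone), with the cohesion gene ord at 4.64 ± 1.06 and the Polo inhibitor mtrm at -4.26 ± 0.42. Together these had a median of -0.02 (adjusted p = 0.863). Of 20 pericentric heterochromatin genes 1 rose and 2 fell (1 and 1 adjusted over the list alone). For the list the median was -0.04 (adjusted p = 0.764). The medians of chromosomes X, 2L, 2R, 3L and 3R were -0.04, 0.06, 0.06, 0.01 and 0.02 (adjusted p = 0.588, 0.923, 0.863, 0.923 and 0.923). Of the 82 cytoplasmic ribosomal protein genes 3 rose and 4 fell (3 and 3 adjusted over the list alone). The median over the list was -0.79 (adjusted p = 9.59e-05, and adjusted p = 0.862 with an estimated correlation). It turned to 0.17 without NGVP16 control 1, the library rich in their RNA (adjusted p = 0.345, range over the settings 8.6e-21 to 0.862), and was -1.35 without control 2. ord was at 0 counts in NGVP16 control 1, so its fitted value without control 2 (11.17) is no bound.

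In SETDB1 GKD 1373 genes were higher and 1069 lower than in the NGVP16 pair, 2442 of 10790 in all. Of these 1344 and 987 changed at least 2-fold, and 3925 genes had an unadjusted p under 0.05. The total was 1124 without SETDB1 GKD 1, 1515 without SETDB1 GKD 2 and 4056 without NGVP16 control 2. With ribosomal protein scaling 744 were higher and 118 lower, with the gene length trend and library level removed 1477 and 2426, without the adult pair 1477 and 961, and without that pair and NGVP16 control 1 1326 and 1201. Of the lists, 16 were called at the preset correlation and 0 with an estimated one.

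**Figure D2:**
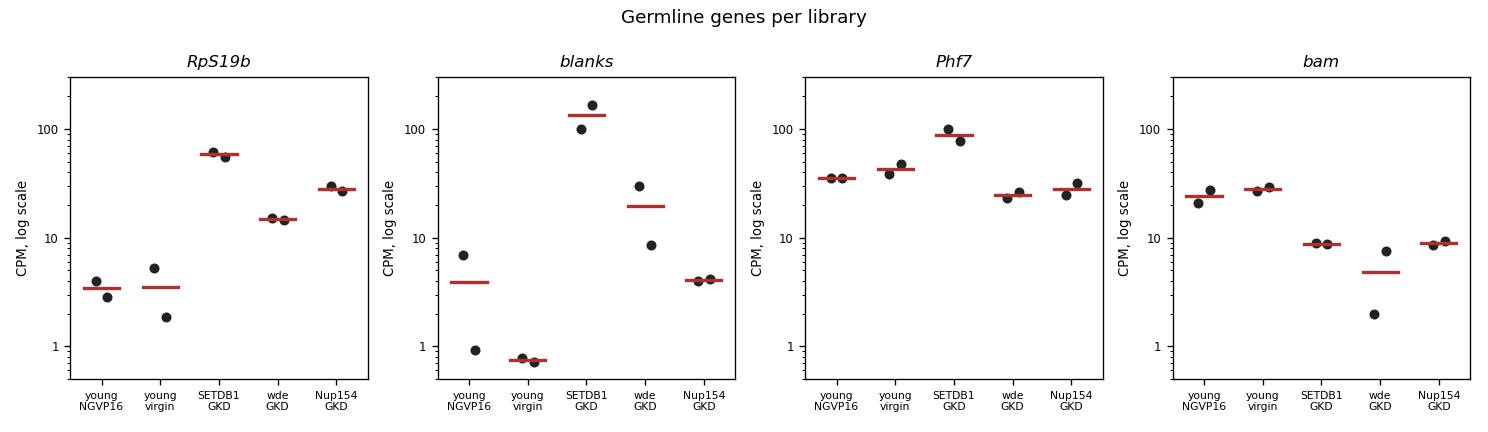
Levels of RpS19b, blanks, Phf7 and bam in CPM on a log axis for each library, by set. In SETDB1 GKD RpS19b is at 58.5 CPM and blanks at 134, against 3.41 and 3.93 in the NGVP16 pair.

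The libraries labelled wde GKD were compared with the same controls to see whether the same genes differ. RpS19b rose to 14.9 CPM ± 0.266 (2.13 ± 0.43, adjusted p = 0.00389), while blanks was at 19.4 CPM ± 15.3 (2.35 ± 0.83, adjusted p = 0.0557) and Phf7 at 24.9 CPM (-0.50, adjusted p = 0.256). bam fell by 2.34 ± 0.56 (adjusted p = 0.0107), with an adjusted p of 0.0512 without wde GKD 1 and a change of -3.6 without wde GKD 2 (range over the settings 0.00185 to 0.147). Syt4, a synaptotagmin, rose to 53.9 CPM ± 5.63 from 0.379 (7.05 ± 0.58), Ugt37B1 was at least 116-fold higher, and Sr-CIV, a scavenger receptor, at least 125.5-fold. Osi19, a gene of the Osiris family, was higher by a ratio of 513 (142 to 4241), and RpL22-like rose to 14.5 CPM ± 4.09 (5.82 ± 0.70). ATPsynepsilonL (6.63 ± 0.86) rose as well, and NGVP16 control 1 held 0 counts of it and of RpL22-like, so that without control 2 no fold can be given. The digestive enzyme genes zetaTry, LManIII, Mal-A3 and Jon99Fi, 4 of the 10 largest rises, each lost the call without wde GKD 1 (adjusted p = 0.186, 0.157, 0.0992 and 0.142), without NGVP16 control 1 (0.176, 0.219, 0.166 and 0.14) and without control 2 (0.166, 0.182, 0.135 and 0.0837), within ranges of 0.0253 to 0.186, 0.00618 to 0.219, 9.73e-05 to 0.196 and 0.00278 to 0.142.

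Oocyte, eggshell, meiosis and piRNA genes were lower in wde GKD. Of 33 oocyte and maternal mRNAs 26 fell (27 adjusted over the list alone), such as pgc, which silences transcription in germ cells (-6.17 ± 0.58), and plu, a cell cycle gene of the egg (-5.12 ± 0.59). Across the list the median was -3.18 (adjusted p = 3.1e-13, and adjusted p = 0.0748 with an estimated correlation). Of 24 eggshell genes 17 fell (17 adjusted over the list alone). The list median was -5.13 (adjusted p = 1.1e-07, and adjusted p = 0.248 with an estimated correlation), and -3.16 without NGVP16 control 1. The chorion genes Cp36 (-9.53 ± 0.99), Cp38 (-8.75 ± 1.21) and Cp7Fb (-6.30 ± 0.63) fell. Of 33 piRNA pathway genes 18 fell and 0 rose (21 fell adjusted over the list alone): rhi, which licenses piRNA clusters, fell to 4.96 CPM from 45.2 (-3.18 ± 0.33) and the Piwi protein gene AGO3 fell by 2.43 ± 0.37. Over the list the median was -1.18 (adjusted p = 1.83e-07, and adjusted p = 0.358 with an estimated correlation). Of 24 meiosis genes 9 fell (9 adjusted over the list alone), such as mtrm (-3.64 ± 0.40) and the recombination gene spn-B (-3.39 ± 0.68). As a list these had a median of -0.91 (adjusted p = 0.0026, and adjusted p = 0.287 with an estimated correlation), and -0.54 without NGVP16 control 2. With ribosomal protein scaling the piRNA and meiosis medians were -0.39 and -0.19. Of 18 germ cell genes 2 rose and 6 fell (3 and 6 adjusted over the list alone). Together these had a median of -0.53 (adjusted p = 0.255), turning to 0.18 with ribosomal protein scaling. Of 20 testis-enriched genes 2 rose and 2 fell (0 and 1 adjusted over the list alone). For the list the median was 1.46 (adjusted p = 0.764). Of 5 yolk genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), where yl fell by 4.00 ± 0.56. The median over the list was -0.07 (adjusted p = 0.487). Yp3, at 1.5 (adjusted p = 0.0485), lost its call without wde GKD 2 (0.308), NGVP16 control 1 (0.0645) or control 2 (0.174, range over the settings 0.00692 to 0.65) and was at -1.34 against the virgin pair.

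In wde GKD muscle genes held 2.75% of the counts. Of 24 muscle genes 19 rose (21 adjusted over the list alone), with Mhc at 3447 CPM ± 316. Across the list the median was 2.42 (adjusted p = 1.44e-10, and adjusted p = 0.0748 with an estimated correlation). Of 12 hemocyte genes 10 rose (10 adjusted over the list alone), with Pxn at 1103 CPM ± 96.5. The list median was 3.48 (adjusted p = 6.53e-08, and adjusted p = 0.0748 with an estimated correlation). Of 15 niche genes 9 rose (10 adjusted over the list alone, median 1.75, adjusted p = 0.000424, and adjusted p = 0.287 with an estimated correlation), and of 20 follicle cell genes 6 rose (6 adjusted over the list alone, median 0.77, adjusted p = 0.00239, and adjusted p = 0.553 with an estimated correlation), with Fas3 at 3.16 ± 0.32. The follicle cell median was 0.51 without NGVP16 control 1 and 1.65 without control 2. Of 9 reproductive tract genes 8 rose (8 adjusted over the list alone). Over the list the median was 2.91 (adjusted p = 6.53e-05, and adjusted p = 0.0748 with an estimated correlation). Of 21 neuronal genes 6 rose and 1 fell (6 and 1 adjusted over the list alone). As a list these had a median of 2.04 (adjusted p = 0.0026, and adjusted p = 0.533 with an estimated correlation). Of 16 fat body genes 5 rose (5 adjusted over the list alone), with the lipoprotein gene apolpp at 4.61 ± 0.70. Together these had a median of 1.54 (adjusted p = 0.0386, and adjusted p = 0.553 with an estimated correlation). The fat body call ended without wde GKD 1 (adjusted p = 0.0742, median 0.62), NGVP16 control 1 (0.083) or control 2 (0.214, range over the settings 0.00096 to 0.553), and with ribosomal protein scaling (0.0752, median 2.42).

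Of 21 H3K9 and heterochromatin factors 7 fell in wde GKD (7 adjusted over the list alone). For the list the median was -0.68 (adjusted p = 0.0107, and adjusted p = 0.533 with an estimated correlation), and -0.13 without NGVP16 control 2 (adjusted p = 0.317, range over the settings 2.82e-05 to 0.533) and -0.04 with ribosomal protein scaling. Of 90 genes on chromosome 4, 21 rose and 2 fell (20 and 2 adjusted over the list alone). The median over the list was 0.46 (adjusted p = 0.00373, and adjusted p = 0.553 with an estimated correlation), 0.52 without NGVP16 control 1 (adjusted p = 0.054, range 3.11e-06 to 0.553) and 1.07 without control 2. Of 20 pericentric genes 2 rose and 5 fell (2 and 5 adjusted over the list alone). Across the list the median was -0.36 (adjusted p = 0.24), turning to 0.4 with ribosomal protein scaling. The medians of chromosomes X, 2L, 2R, 3L and 3R were -0.17, 0.03, 0, 0 and -0.01 (adjusted p = 0.209, 0.619, 0.751, 0.946 and 0.986), with X at 0.03 by DESeq2 size factors and 0.59 by ribosomal protein scaling. Of 82 ribosomal protein genes 3 rose and 13 fell (3 and 4 adjusted over the list alone). The list median was -1.20 (adjusted p = 6.24e-07, and adjusted p = 0.655 with an estimated correlation), and -0.11 without NGVP16 control 1 (adjusted p = 0.278, range 1e-23 to 0.655).

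In wde GKD 1914 genes were higher and 1881 lower, 3795 in all, of which 1852 and 1673 changed at least 2-fold, and 5096 had an unadjusted p under 0.05. The total was 1559 without wde GKD 1 and 2455 without wde GKD 2. With DESeq2 size factors 2229 were higher and 1292 lower, with ribosomal protein scaling 1800 and 136, with the gene length trend and library level removed 1869 and 3391, without the adult pair 2150 and 1438, and without that pair and NGVP16 control 1 1833 and 1829. Of the lists 20 were called, and 0 with an estimated correlation.

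Nup154 GKD was compared with the same controls, as the knockdown of a gene outside H3K9 methylation. RpS19b rose to 28.3 CPM ± 2.33 (3.06 ± 0.44, adjusted p = 0.000545), while blanks was at 4.08 CPM ± 0.0831 (0.10 ± 0.83, adjusted p = 0.953), Phf7 at 28.3 CPM (-0.31, adjusted p = 0.491) and bam at -1.43 ± 0.54 (adjusted p = 0.0658). Among the largest rises from a control at 0 counts, SPR, the sex peptide receptor, was at 77.0 CPM ± 6.87 and at least 507-fold higher, Send1, a secreted protease of the spermatheca, was at least 253-fold higher, and the odorant-binding protein gene Obp57a was at least 550-fold higher. Ugt307A1 was at least 121-fold and the cadherin gene CadN2 at least 94.2-fold higher. stol, a calcium channel subunit, rose to 159 CPM ± 10.1 from 0.382 (8.73 ± 0.43, adjusted p = 1.51e-05), although it overlaps other genes on its strand. The largest falls included the fat body genes Fbp1 (-7.81 ± 0.94) and Lsp1gamma (-6.65 ± 1.15), the vitelline membrane gene Vm26Ac (-6.88 ± 0.77), the kinase Mos (-5.05 ± 0.71) and dhd (-5.14 ± 0.61). Fbp2 fell by 6.61 ± 1.17, and Nup154 GKD 2 held 0 counts of it, so that its fitted change without Nup154 GKD 1 (-11.51) is no bound. zetaTry, at least 80.6-fold higher, lost its call in every left-out fit (adjusted p = 0.112 without Nup154 GKD 1, 0.125 without 2, 0.175 and 0.167 without NGVP16 controls 1 and 2, range over the settings 0.0158 to 0.175).

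Of 33 oocyte and maternal mRNAs 25 fell and 1 rose in Nup154 GKD (26 and 2 adjusted over the list alone), the rise being capu, an actin nucleator (1.46 ± 0.29). Over the list the median was -2.50 (adjusted p = 8.32e-09, and adjusted p = 0.278 with an estimated correlation). Of 24 eggshell genes 13 fell (14 adjusted over the list alone), in libraries with an eggshell share of 0.068%. As a list these had a median of -3.15 (adjusted p = 0.000165, and adjusted p = 0.526 with an estimated correlation). Of 33 piRNA pathway genes 16 fell and 2 rose (18 and 2 adjusted over the list alone), with squ at -3.01 ± 0.27, a gene that overlaps grp on the same strand. Together these had a median of -0.73 (adjusted p = 0.000164, and adjusted p = 0.712 with an estimated correlation), and -0.42 with ribosomal protein scaling. Of 24 meiosis genes 2 rose and 7 fell (3 and 8 adjusted over the list alone, median -0.37, adjusted p = 0.169), of 18 germ cell genes 1 rose and 5 fell (1 and 5 adjusted over the list alone, median -0.09, adjusted p = 0.488, turning to 0.06 with ribosomal protein scaling), and of 5 yolk genes 2 fell (2 adjusted over the list alone, median -1.03, adjusted p = 0.272). Of 20 testis-enriched genes 1 rose and 2 fell (0 and 2 adjusted over the list alone; adjusted p = 0.927), and their median of 0.64 lay above 0 while the test ranked them down. Of 21 H3K9 and heterochromatin factors 7 fell (7 adjusted over the list alone). For the list the median was -0.72 (adjusted p = 0.0117, and adjusted p = 0.712 with an estimated correlation), and -0.13 without NGVP16 control 2 (adjusted p = 0.347, range over the settings 3.81e-05 to 0.712).

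Of 24 muscle genes 19 rose in Nup154 GKD (21 and 1 lower adjusted over the list alone), with muscle genes at 2.72% of the counts and the muscle protein gene Mp20 at 3.24. The median over the list was 2.44 (adjusted p = 1.08e-09, and adjusted p = 0.104 with an estimated correlation). Of 12 hemocyte genes 9 rose (9 adjusted over the list alone), with Pxn at 2195 CPM ± 77.6. Across the list the median was 2.49 (adjusted p = 6.81e-06, and adjusted p = 0.158 with an estimated correlation). Of 9 reproductive tract genes 8 rose (8 adjusted over the list alone). The list median was 4.08 (adjusted p = 2.57e-05, and adjusted p = 0.104 with an estimated correlation). Of 15 niche genes 8 rose (10 adjusted over the list alone, median 1.79, adjusted p = 0.000433, and adjusted p = 0.364 with an estimated correlation), and of 20 follicle cell genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.13, adjusted p = 0.00312, and adjusted p = 0.737 with an estimated correlation), with the transcription factor cas at 3.20 ± 0.37. The follicle cell median was 0.73 without NGVP16 control 1 and 1.79 without control 2. Of 16 fat body genes 3 rose and 6 fell (4 and 6 adjusted over the list alone; adjusted p = 0.585), with a median of 0.32 but a mean of -0.70. Of 21 neuronal genes 5 rose and 2 fell (5 and 2 adjusted over the list alone). Over the list the median was 0.82 (adjusted p = 0.623). Of 90 genes on chromosome 4, 17 rose and 7 fell (13 and 4 adjusted over the list alone, median 0.15, adjusted p = 0.323), and of 20 pericentric genes 1 rose and 5 fell (1 and 5 adjusted over the list alone, median -0.45, adjusted p = 0.14). The medians of chromosomes X, 2L, 2R, 3L and 3R were -0.07, 0, 0, 0 and 0 (adjusted p = 0.623, 0.974, 0.653, 0.974 and 0.989). Of 82 ribosomal protein genes 2 rose and 9 fell (2 and 2 adjusted over the list alone). As a list these had a median of -0.80 (adjusted p = 0.00312, and adjusted p = 0.907 with an estimated correlation). It turned to 0.26 without NGVP16 control 1 (adjusted p = 0.13, range 4.84e-15 to 0.907) and was -1.35 without control 2.

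In Nup154 GKD 1894 genes were higher and 1847 lower, 3741 in all, of which 1821 and 1701 changed at least 2-fold, and 4893 had an unadjusted p under 0.05. The total was 1904 without Nup154 GKD 1 and 1869 without Nup154 GKD 2. With ribosomal protein scaling 1185 were higher and 335 lower, with the gene length trend and library level removed 1836 and 2994, without the adult pair 2104 and 1631, and without that pair and NGVP16 control 1 1778 and 2018. Of the lists 13 were called, and 0 with an estimated correlation.

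**Figure D3:**
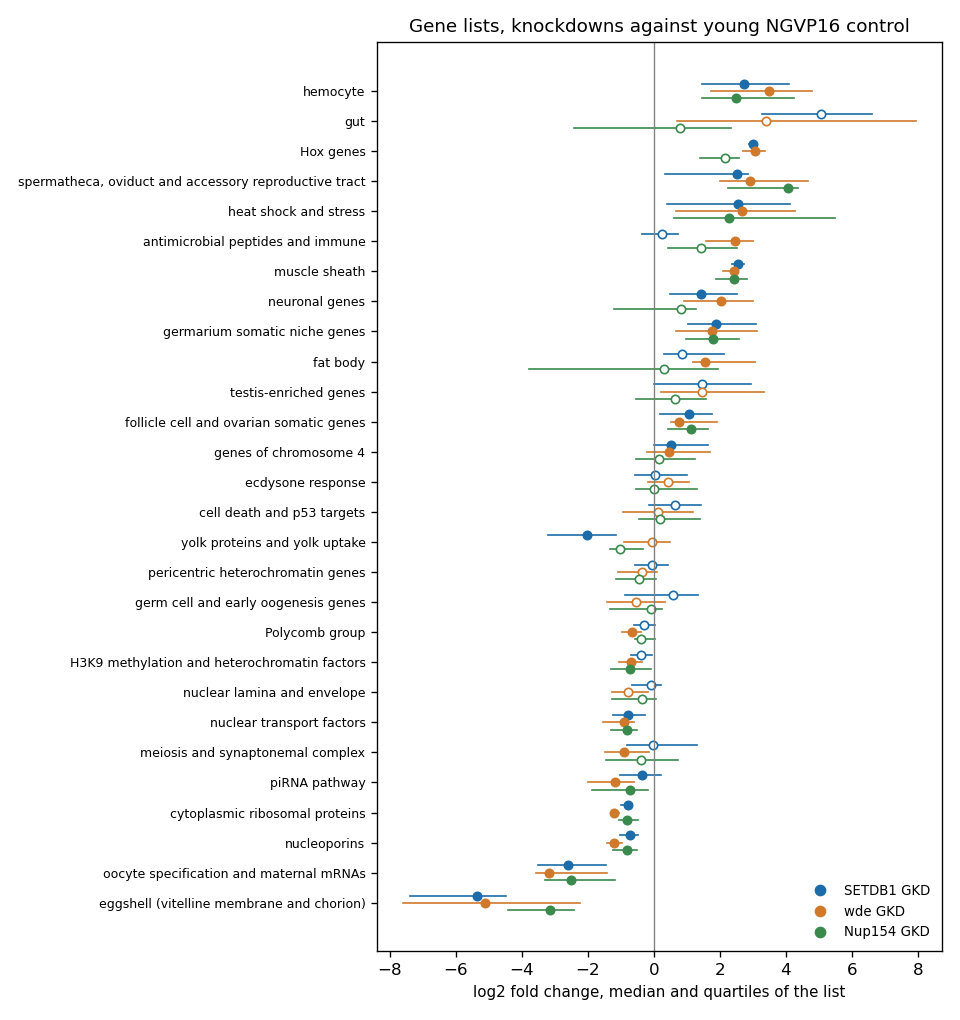
Median log2 fold change (horizontal axis) of each gene list (of the chromosomes only 4) against the NGVP16 pair, with the quartiles of its genes as bars, for each knockdown, filled where the camera adjusted p was below 0.05 at the preset correlation. Muscle lists lie at 2.56, 2.42 and 2.44, and oocyte lists at -2.61, -3.18 and -2.50; 0 lists were called with an estimated correlation.

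Nucleoporin genes, a list included because the study is known to have examined them and so not independent evidence of its direction, were lower in each knockdown. In wde GKD 22 of the 29 tested fell and 0 rose (25 fell adjusted over the list alone), with a median of -1.22 (adjusted p = 3.64e-08, and adjusted p = 0.0748 with an estimated correlation). In Nup154 GKD 11 fell, the targeted Nup154 among them (12 adjusted over the list alone, median -0.81, adjusted p = 4.33e-05, and adjusted p = 0.278 with an estimated correlation). Without Nup154 in the list, a test chosen after the results were seen, 10 of 28 fell there (11 adjusted over the list alone) with a median of -0.81 (adjusted p = 8.56e-05, and adjusted p = 0.278 with an estimated correlation). In SETDB1 GKD 5 fell (5 adjusted over the list alone, median -0.72, adjusted p = 1.75e-05, and adjusted p = 0.174 with an estimated correlation), with a median of -0.43 without NGVP16 control 2. Nup50 and Nup54 fell in all 3: Nup50 by 1.54 ± 0.27, 1.76 ± 0.27 and 1.77 ± 0.27, and Nup54 by 1.57 ± 0.27, 1.71 ± 0.27 and 1.72 ± 0.27 in SETDB1, wde and Nup154 GKD. In wde GKD Nup43 (-1.96 ± 0.34), Rae1 (-1.63 ± 0.31) and Nup107 (-1.34 ± 0.27) fell too. These 5 calls of the 22 held with any library left out, as did 2 of 5 in SETDB1 GKD and 2 of 11 in Nup154 GKD, the 2 being Nup50 and Nup54, whose calls ended with ribosomal protein scaling (adjusted p = 0.214 and 0.225 in SETDB1 GKD, 0.23 and 0.27 in wde GKD, 0.0873 and 0.108 in Nup154 GKD, the highest of ranges that start at 2.27e-08 or lower). Of the others in wde GKD, Nup133 and Nup160 lost the call without wde GKD 1 (adjusted p = 0.105 and 0.152, ranges over the settings 0.000439 to 0.662 and 0.000368 to 0.585). In SETDB1 GKD, Nup107 (-1.16 ± 0.26), Aladin (-1.03 ± 0.28) and Rae1 (-1.0 ± 0.30) lost it without SETDB1 GKD 1 or 2, and Rae1 also without NGVP16 control 1. Over the settings their adjusted p reached down to 1.7e-05, 0.000764 and 0.00781, and up to 0.487 for Nup107 and 0.582 for Aladin. The list median stayed below 0 under each scaling, at -0.32, -0.49 and -0.50 with ribosomal protein scaling, while mbo and Sec13 turned to 0.08 and 0.12 in wde GKD. Eggshell genes took a smaller share of the counts in the same libraries.

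Nuclear transport factors were also lower. Of 18, 5 fell in SETDB1 GKD (7 adjusted over the list alone, median -0.78, adjusted p = 0.00394, and adjusted p = 0.371 with an estimated correlation), 9 in wde GKD (9 adjusted over the list alone, median -0.90, adjusted p = 0.000731, and adjusted p = 0.287 with an estimated correlation) and 6 in Nup154 GKD (6 adjusted over the list alone, median -0.80, adjusted p = 0.00814, and adjusted p = 0.526 with an estimated correlation). Their medians were -0.48, -0.23 and -0.54 with ribosomal protein scaling. Rcc1, which loads Ran with GTP, fell by 1.97 ± 0.31, 2.34 ± 0.31 and 2.24 in the 3 knockdowns. Without NGVP16 control 2 the list was at -0.31 in SETDB1 GKD (adjusted p = 0.0644, range over the settings 2.56e-05 to 0.371) and at -0.40 in Nup154 GKD (adjusted p = 0.0551, range 5.51e-05 to 0.526). Of 10 lamina and envelope genes 1 fell in SETDB1 GKD (1 adjusted over the list alone, median -0.08, adjusted p = 0.601), 1 rose and 2 fell in wde GKD (1 and 2 adjusted over the list alone, median -0.77, adjusted p = 0.15), and 2 rose and 3 fell in Nup154 GKD (2 and 3 adjusted over the list alone, median -0.35, adjusted p = 0.531). These medians were 0.24, -0.11 and -0.25 with ribosomal protein scaling.

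**Figure D4:**
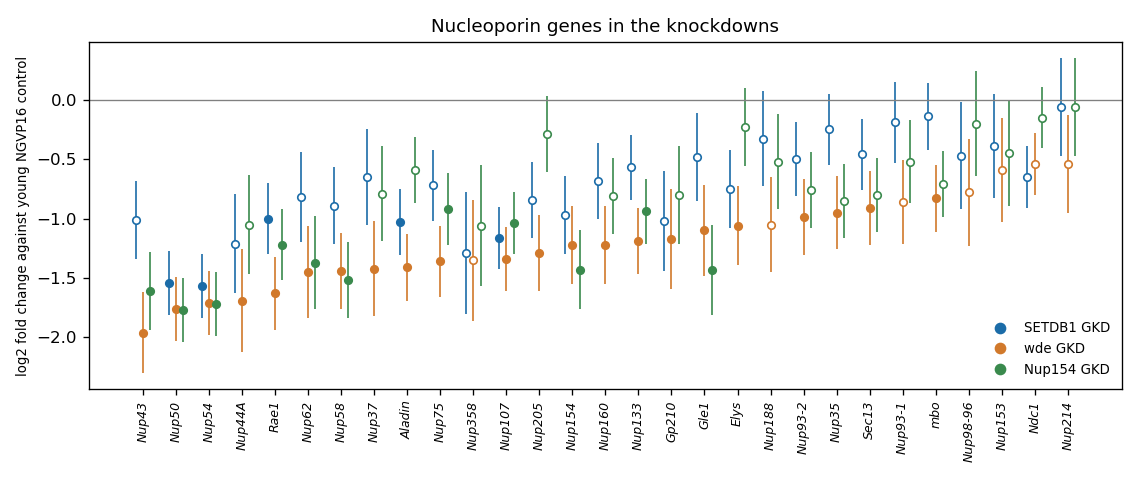
Log2 fold change against the NGVP16 pair (vertical axis, bars are SE) of the nucleoporin genes tested in each knockdown, filled where the adjusted p was below 0.05. Medians are -0.72, -1.22 and -0.81 in SETDB1, wde and Nup154 GKD; mbo and Sec13 turn to 0.08 and 0.12 in wde GKD with ribosomal protein scaling.

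Direct comparison of SETDB1 GKD with wde GKD asked where an enzyme and its cofactor differ. RpL22-like was higher in SETDB1 GKD (155 CPM ± 44.3 against 14.5 ± 4.09; 3.42 ± 0.52, adjusted p = 0.0301), as was rhi (22.9 CPM ± 5.23 against 4.96; 2.21 ± 0.32, adjusted p = 0.0258), which overlaps another gene on its strand. Sgp was lower by -4.59 ± 0.62 on the log2 scale (adjusted p = 0.0141). RpS19b was at 1.98 (adjusted p = 0.0782), blanks at 2.79 ± 0.81 (adjusted p = 0.193) and Phf7 at 1.84 ± 0.34 (adjusted p = 0.0589). In all 13 genes were higher and 14 lower, 27 of the 1387 with an unadjusted p under 0.05, but the split was 22 and 108 without SETDB1 GKD 1, 5 and 24 without wde GKD 1, and 180 and 357 with DESeq2. The list tests between knockdowns were added after the data had been seen, and 6 of the 13 lists called here kept the call with any library left out. Germ cell genes (median 0.88, adjusted p = 3.61e-07, and adjusted p = 0.319 with an estimated correlation), meiosis genes (1.08, adjusted p = 2.71e-08, and adjusted p = 0.27 with an estimated correlation), piRNA genes (0.85, adjusted p = 1.52e-11, and adjusted p = 0.319 with an estimated correlation), nucleoporins (0.48, adjusted p = 0.00017, and adjusted p = 0.319 with an estimated correlation) and H3K9 and heterochromatin factors (0.51, adjusted p = 0.00249, and adjusted p = 0.559 with an estimated correlation) ranked higher in SETDB1 GKD, and yolk genes lower (-2.50, and -1.54 without wde GKD 2; adjusted p = 0.00243, and adjusted p = 0.319 with an estimated correlation). With ribosomal protein scaling the medians of germ cell genes, meiosis genes, piRNA genes, nucleoporins and H3K9 and heterochromatin factors were 0.5, 0.74, 0.52, 0.1 and 0.11. The calls of RpL22-like and rhi ended without SETDB1 GKD 2 (0.0673 and 0.154), wde GKD 1 (0.114 and 0.168) or wde GKD 2 (0.217 and 0.14), within ranges of 1.42e-07 to 0.417 and 4.49e-08 to 0.462, and that of Sgp without SETDB1 GKD 2 (0.12, range 1.29e-09 to 0.15). The DESeq2 test called 537 genes and limma voom 362. The count was 130 without SETDB1 GKD 1, 14 without SETDB1 GKD 2, 8 without wde GKD 2, 2 higher and 5 lower with ribosomal protein scaling, 16 and 13 without the adult pair, and 159 and 141 without that pair and NGVP16 control 1.

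SETDB1 GKD was compared with Nup154 GKD to separate what differs in SETDB1 GKD from what both share. blanks was higher in SETDB1 GKD (134 CPM ± 47.6 against 4.08 ± 0.0831; 5.03 ± 0.90, adjusted p = 0.0256), as was Phf7 (1.65 ± 0.34, adjusted p = 0.0292), while RpS19b was at 1.05 (adjusted p = 0.164). Nox, an NADPH oxidase, was lower in SETDB1 GKD (13.4 CPM ± 5.36 against 194 ± 12.5; -3.85 ± 0.34, adjusted p = 0.000407), as was yellow-d (-4.86 ± 0.52, adjusted p = 0.00204). Fbp1 was higher by 8.54 ± 0.96 and Lsp1gamma by 7.54 ± 1.17, both storage protein genes of the fat body. hog was at least 104-fold higher, though it overlaps NetB on its strand, and TfIIA-S-2 was higher by a ratio of 718 (128 to 28380). In all 143 genes were higher and 222 lower, 365 of the 2271 with an unadjusted p under 0.05. Of the 11 lists called, the 5 that kept the call with any library left out were germ cell genes (median 0.63, adjusted p = 0.000648, and adjusted p = 0.706 with an estimated correlation), piRNA genes (0.57, adjusted p = 0.000648, and adjusted p = 0.81 with an estimated correlation), chromosome 4 (0.47, adjusted p = 0.00111, and adjusted p = 0.81 with an estimated correlation), eggshell genes (-2.35, adjusted p = 6.32e-05, and adjusted p = 0.81 with an estimated correlation) and reproductive tract genes (-0.92, adjusted p = 0.000939, and adjusted p = 0.34 with an estimated correlation). Without Nup154 GKD 1 or 2 the calls of blanks (adjusted p = 0.253 each, range over the settings 9.22e-07 to 0.253), Phf7 (0.285 and 0.201, range 1.96e-06 to 0.323), Fbp1 (0.0842 and 0.0709, range 6.43e-20 to 0.0842), Lsp1gamma (0.161 and 0.144, range 1.01e-09 to 0.161), hog (0.158 and 0.149, range 2.03e-05 to 0.158) and TfIIA-S-2 (0.119 and 0.0957, range 6.03e-06 to 0.119) ended, and without SETDB1 GKD 2 those of blanks (0.0773), Phf7 (0.0847) and hog (0.076), with Phf7 also lost without SETDB1 GKD 1 (0.102). The DESeq2 test called 1261 genes and limma voom 936. The count was 13 and 18 without Nup154 GKD 1 or 2, 145 and 55 without SETDB1 GKD 1 or 2, 18 higher and 12 lower with ribosomal protein scaling, 136 and 236 without the adult pair, and 730 and 770 without that pair and NGVP16 control 1.

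wde GKD and Nup154 GKD differed in single genes and in lists. Fbp1 was higher in wde GKD (184 CPM ± 150 against 0.364; 8.94 ± 0.97, adjusted p = 0.00434), and so were the storage protein gene Lsp1gamma (8.20 ± 1.19) and the fat body gene Fbp2 (7.40 ± 1.20). stol was lower in wde GKD (17.9 CPM ± 1.98 against 159 ± 10.1; -3.15 ± 0.30, adjusted p = 0.00434), and so was Cp36 (-5.12 ± 0.89). RpS19b was at -0.93 (adjusted p = 0.257). In all 108 genes were higher and 72 lower, 180 of the 1879 with an unadjusted p under 0.05. Of the 10 lists called, the 3 that kept the call with any library left out were fat body genes (median 1.88, adjusted p = 0.000138, and adjusted p = 0.767 with an estimated correlation), neuronal genes (1.01, adjusted p = 0.000608, and adjusted p = 0.815 with an estimated correlation) and chromosome 4 (0.30, adjusted p = 0.00178, and adjusted p = 0.815 with an estimated correlation). The gene calls ended without Nup154 GKD 1 or 2 for Fbp1 (adjusted p = 0.101 and 0.0981), Lsp1gamma (0.203 and 0.186), Fbp2 (0.096 and 0.154), stol (0.0612 and 0.0558) and Cp36 (0.175 and 0.0981), and for Fbp2 also without wde GKD 1 (0.0725) and for Cp36 without wde GKD 1 or 2 (0.184 and 0.0882), within ranges of 1.15e-21 to 0.101, 1.97e-11 to 0.203, 4.47e-10 to 0.154, 9.25e-20 to 0.0806 and 4.6e-07 to 0.184. The DESeq2 test called 899 genes and limma voom 637. The count was 2 without Nup154 GKD 1, 0 without Nup154 GKD 2 (edgeR, with 1071 at an unadjusted p under 0.05), 19 and 55 without wde GKD 1 or 2, 10 higher and 3 lower with ribosomal protein scaling, 229 and 316 with the gene length trend and library level removed, 263 and 270 with the trend alone removed, 88 and 55 without the adult pair, and 368 and 407 without that pair and NGVP16 control 1.

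Genes called in one knockdown were often called in another. SETDB1 GKD and wde GKD shared 1154 higher and 928 lower genes (244 and 186 for independent calls, 2 went opposite ways). SETDB1 GKD and Nup154 GKD shared 1108 and 877 (241 and 183, 3 opposite), and wde GKD and Nup154 GKD shared 1353 and 1380 (336 and 322, 12 opposite). In all 3 knockdowns 1019 genes were higher (among them RpS19b, Pxn and Fas3) and 810 lower (dhd, exu and Nup50). The shared controls add to such an overlap. In 20 simulations of unchanged groups with the same controls, at most 1 gene was shared. Unchanged groups give few calls, so this cannot exclude an overlap from the controls. Log2 fold changes had r = 0.517 against 0.843 measured for SETDB1 and wde GKD (covariance 0.233 against 3.105), 0.515 against 0.704 for SETDB1 and Nup154 GKD (0.233 against 2.637), and 0.511 against 0.765 for wde and Nup154 GKD (0.231 against 3.23), over 9908 genes. With the controls split, 1 knockdown against the NGVP16 pair and the other against the virgin pair, r was 0.646 and 0.701, 0.613 and 0.433, and 0.725 and 0.495, and the shared totals were 1970 and 2243, 1989 and 1866, and 2845 and 2398. Without NGVP16 control 2 the shared totals were 3501 for SETDB1 and wde GKD and 3400 for SETDB1 and Nup154 GKD. The split of shared genes was 680 higher and 78 lower, 592 and 85, and 995 and 89 with ribosomal protein scaling, and 1197 and 2155, 1137 and 1947, and 1313 and 2556 with the gene length trend and library level removed; for wde and Nup154 GKD it was 1542 and 1038 with DESeq2 size factors.

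The virgin and NGVP16 controls were compared to see how far young controls differ. Dcr-2, which dices long double-stranded RNA, was at 5336 CPM ± 794 in the virgin pair against 128 ± 102 (5.38 ± 0.57, adjusted p = 0.00155), and the title of a virgin library names Dcr. The receptor gene fz (3.18 ± 0.32), the transporter gene Ctl2 (2.85 ± 0.32) and the enzyme gene Oat (3.92 ± 0.49) were higher too, and sordd2 was lower (-6.21 ± 0.53, adjusted p = 0.00109). Hsp70Bb, one of several near-identical Hsp70 copies whose counts are uncertain, was higher (7.68 ± 0.84), with 0 counts in NGVP16 control 1. Cyp309a2 was at -6.02 ± 0.81, and its call ended without virgin control 1 (adjusted p = 0.122) or 2 (0.0719, range over the settings 1.09e-07 to 0.122). In all 38 genes were higher and 178 lower, 216 of the 1773 with an unadjusted p under 0.05. The count was 2205 without NGVP16 control 2, 24 without virgin control 1 and 26 without virgin control 2, and the split was 6 and 52 with ribosomal protein scaling, 350 and 269 with the gene length trend and library level removed, 195 and 323 with the trend alone removed, 36 and 130 without the adult pair, and 64 and 264 without that pair and NGVP16 control 1.

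The adult pair held its counts in other genes than all other libraries. Antisense RNA genes took 39.1% and 40.7% of its counts, and ribosomal protein genes, abundant in every other library, 0.441% ± 0.0593 against 14.4% ± 2.41 in the virgin pair. The ribosomal protein genes RpL41, RpS3A, sta, RpLP0 and RpL7A were at 0 counts, as was egg. The largest rises, NijB, Roc1b, ppk19, Pal2 and Cyp303a1, all lie opposite another gene. With these limits, 2409 genes were higher and 5145 lower than in the virgin pair, 7554 in all (7725 with an unadjusted p under 0.05), 4042 and 705 with ribosomal protein scaling and 3214 and 3930 with upper quartile scaling, and no biology is read from them.

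**Figure D5:**
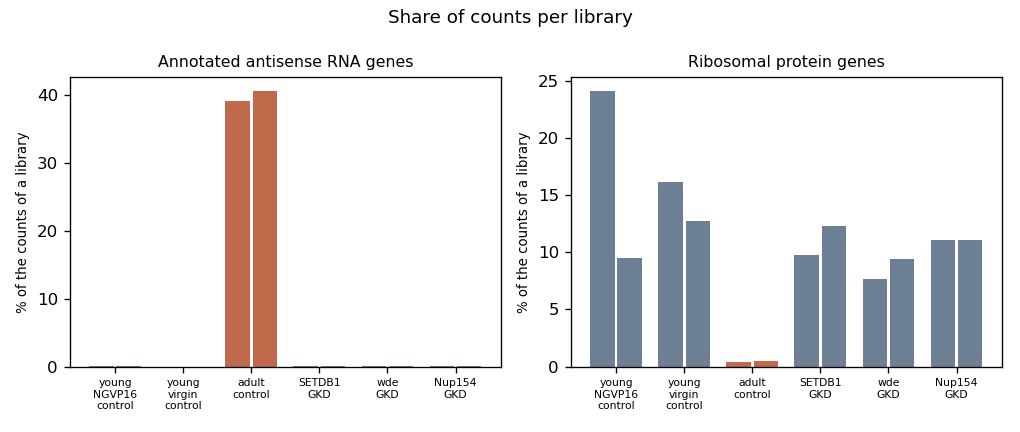
Percent of counts in antisense RNA genes and in cytoplasmic ribosomal protein genes (vertical axes), with 1 bar per library. The adult libraries hold 39.1% and 40.7% antisense counts, and NGVP16 control 1 holds 24.1% ribosomal protein counts against 9.5% in NGVP16 control 2.

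Some named genes overlap another gene on the same strand, among them HP6, hog, rhi, mtrm, squ, Boot, stol, Con, CadN2, Fas3 and Su(var)3-9, and others, such as bam, Cp36, Cp38, Cp7Fb, Cp7Fc, Nup50, Nup54, Nup107 and Dcr-2, on the opposite strand, so their counts are less certain.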

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

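The tests of differences between knockdowns on whole gene lists, and all tests of explanations here except the strand correlation, were chosen after the results were seen. The 16 differences below passed the test between 2 knockdowns, and their list or gene was called against control in either but not both. The adult pair stood out by counts in genes near 0 elsewhere. Each list call between knockdowns given here was lost with an estimated correlation, where the adjusted p ran from 0.27 to 0.817.

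SETDB1 GKD and wde GKD differed in germline and body lists. Meiosis genes (median 1.08) and H3K9 and heterochromatin factors (0.51) lay higher in SETDB1 GKD, with the second at 0.11 with ribosomal protein scaling, and yolk genes (-2.50) lower, with -1.54 without wde GKD 2. Polycomb group genes were at 0.40, with an adjusted p of 0.05 without SETDB1 GKD 2 and 0.0672 without wde GKD 2 (range over the settings 0.00676 to 0.688), and at 0.01 with ribosomal protein scaling. Antimicrobial and immune genes were at -2.42 and rested on wde GKD 1, since without it they were at -0.32 (adjusted p = 0.447, range 1.38e-13 to 0.637). Fat body genes were at -0.74, but at 0.01 without wde GKD 1, -1.19 without wde GKD 2, -1.54 without SETDB1 GKD 1, and -0.33 without SETDB1 GKD 2 (adjusted p = 0.288, range 0.000124 to 0.559).

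SETDB1 GKD and Nup154 GKD differed in blanks (5.03) and Phf7 (1.65). Neither passed between SETDB1 GKD and wde GKD (adjusted p = 0.193 and 0.0589). Without Nup154 GKD 1 or 2 the adjusted p against Nup154 GKD was 0.253 for blanks, and 0.285 and 0.201 for Phf7. Without SETDB1 GKD 2 it was 0.0773 and 0.0847, and without SETDB1 GKD 1 it was 0.102 for Phf7, within ranges of 9.22e-07 to 0.253 and 1.96e-06 to 0.323. Genes on chromosome 4 were at 0.47. H3K9 and heterochromatin factors were at 0.56, and 0.35 without SETDB1 GKD 2 (adjusted p = 0.0709, range 0.00148 to 0.81). Yolk genes were at -1.69, with an adjusted p of 0.061 without SETDB1 GKD 1 and 0.0537 without SETDB1 GKD 2 (range 0.0112 to 0.81). Neuronal genes were at 0.71, but 0.35 without Nup154 GKD 1 (adjusted p = 0.0612) and 0.66 without SETDB1 GKD 1 (adjusted p = 0.0586, range 0.00511 to 0.817).

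wde GKD and Nup154 GKD differed in fat body genes (1.88), neuronal genes (1.01) and genes on chromosome 4 (0.30). Meiosis genes were at -0.54, with -0.44 and an adjusted p of 0.105 without wde GKD 1, and -0.29 without Nup154 GKD 2 (range 0.00181 to 0.815), and at -0.08 with ribosomal protein scaling.

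The adult pair held 39.1% and 40.7% of its counts in antisense RNA genes. Over 295 antisense genes that lie opposite a protein-coding gene, their adult CPM followed the CPM of the opposite gene in the virgin pair (rho = 0.654, permutation p = 1e-04, the smallest that 10000 permutations can give), against 0.335 for antisense CPM within the virgin pair. This is consistent with reads counted on the wrong strand of directional libraries. A true rise of antisense RNA with the sense mRNA kept is argued against by ribosomal protein genes, at 0.441% of adult counts against 14.4% ± 2.41 in the virgin pair. Counts on the other strand were not used here, so a true difference of the adult pair stays untested.

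Muscle genes rose as a list in each knockdown, calls lost with an estimated correlation (adjusted p = 0.14, 0.0748 and 0.104). Muscle genes rose more than follicle cell genes by 1.365, 1.016 and 0.934 (pooled SD of libraries 0.244). Hemocyte medians exceeded muscle medians, so this depends on the list taken and cannot test a lower germline share. The length trend of NGVP16 control 1 is argued against as the whole cause, since the lowest muscle median with the trend removed was 1.941. No test here separates a larger part of muscle sheath in ovaries with less germline from more left by dissection, and both stay open.

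Nucleoporins fell as a list in each knockdown, calls lost with an estimated correlation (adjusted p = 0.174, 0.0748 and 0.278). The length trend of NGVP16 control 1 is argued against as the whole cause, since their highest median without it was -0.643. In SETDB1 GKD they fell by more than the piRNA genes, by -0.367 (SD 0.109). Oocyte and maternal mRNAs had a lower median there than nucleoporins, and meiosis and germ cell genes had higher ones. The result depends on the germline list taken, so it cannot decide whether a lower germline share is the whole cause there. In wde GKD and Nup154 GKD the difference from the piRNA genes was 0.026 and 0.056 (0.028 and 0.077 without Nup154 in the list), so a lower share of germline RNA could account for the fall in those. egg (adjusted p = 0.178) and wde (0.54) did not pass as lower in the libraries labelled by them in the fit to 12. With the length trend alone removed egg passed (0.0154) and wde did not (0.59), as against the virgin pair (0.039 and 0.613). They were at -1.08 and -0.87 without NGVP16 control 1, and -0.04 and 0.78 without control 2. So egg's call rests on the control pair, wde passed with neither, and a direct effect is open and untested.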

How the results depend on the processing

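Of 293 comparisons of a count with its value in another setting, 216 stayed within 1.5 times and 77 moved. Named genes kept their direction and side of the threshold in 7757 of 8930 cases, 879 lost and 281 gained a call and 13 reversed. For lists, the direct comparisons included, these were 4003 of 4344, 211, 118 and 12. The settings added after the data were seen were those without the adult pair, both removals of the length trend, and lists without the targeted genes, where every list call stayed. The first removal also took out each library's level, so the second, made after the calls of the first were seen, was centred. Exon length was known for 97.9% of genes. Except where fewer libraries were used, the cause was not tested.

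Ribosomal protein scaling gave 862, 1936 and 1520 genes for SETDB1, wde and Nup154 GKD, 7 for SETDB1 against wde GKD, 30 for SETDB1 against Nup154 GKD, 13 for wde against Nup154 GKD, 4747 for the adult pair, 58 for the virgin pair and overlaps of 758, 677 and 1084. With only the 4 libraries compared, which leaves 2 residual degrees of freedom, the counts were 486, 1558 and 2244 against control, 1, 2268 and 1979 between knockdowns, and 0 for the virgin pair (edgeR, with 788 at an unadjusted p under 0.05), with overlaps of 395, 397 and 1134. The 8 numbered libraries gave 12, 212 and 93 between knockdowns, the DESeq2 test 537, 1261 and 899 and 908 for the virgin pair, and limma voom 362, 936 and 637. No filter gave 148 for SETDB1 against wde GKD and 327 for wde against Nup154 GKD. A block on the replicate number gave 241 for SETDB1 against Nup154 GKD and 117 for wde against Nup154 GKD, while replicate differences correlated at -0.169 to 0.388 between sets, highest for SETDB1 with wde GKD, so pairing stays open. With the length trend and level removed the counts were 3903 for SETDB1 GKD, 258, 1032 and 545 between knockdowns, 619 for the virgin pair, and overlaps of 3352 and 3084 with SETDB1 GKD. With the trend alone removed they were 229, 1182 and 533, and 518. Without the adult pair and NGVP16 control 1 they were 300, 1500 and 775, and 328.

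With each library left out, the counts were 1124 to 4056 for SETDB1 GKD, 1559 to 4782 for wde GKD, 1869 to 4900 for Nup154 GKD, 8 to 130, 13 to 145 and 0 to 55 between knockdowns, 24 to 2205 for the virgin pair and 6958 to 7142 for the adult pair. Overlaps ran from 1987 to 3501, 1886 to 3400 and 2560 to 3901 without a control.

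Lists called were 0 in each knockdown with an estimated correlation, and 20 in Nup154 GKD with fry. Against the virgin pair Hsp70Bb turned to -0.56 in SETDB1 GKD and -1.18 in wde GKD (-0.19 with all 4 controls), Yp3 in wde GKD to -1.34 (-0.53 with all 4) and VGlut in Nup154 GKD to 0. Ribosomal protein genes turned to 0.26 in Nup154 GKD and 0.17 in SETDB1 GKD without NGVP16 control 1, and to 0.26 and 0.15 without the adult pair as well, and were at -1.35 in both without control 2. Without NGVP16 control 2 Nup98-96 turned to 0.96 in Nup154 GKD and 0.7 in SETDB1 GKD, and wde to 0.9 in Nup154 GKD, 0.78 in wde GKD and 1.07 in the virgin pair, against -0.82 and -1.04, and -0.86, -0.87 and -0.69, without control 1. In wde GKD mbo and Sec13 turned to 0.08 and 0.12 with ribosomal protein scaling. With fry, chromosomes 2L and 3R were called the other way in Nup154 GKD (medians 0 and 0) and 3R in SETDB1 and wde GKD (0.02 and -0.01). For SETDB1 against wde GKD, eggshell genes (-0.24, and 0.92 without wde GKD 2) and oocyte genes (-0.20) turned without wde GKD 1, testis-enriched genes (-1.73) without wde GKD 2, and gut genes (2.67, where the test direction turned) without SETDB1 GKD 2. Testis-enriched genes were at -1.74 without SETDB1 GKD 1 and 1.61 without wde GKD 1, and gut genes at -7.43 and 4.52.

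The adult libraries, at 471770 and 682565 counts, hold too few counts for genes of low level, and the 2 libraries per set limit every test.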

Other observations

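The gene lists were fixed before the files were read, and of the tests here that of duplicate gene copies was added after the largest rises were seen, with its prediction written before its own result. Of 23 heat shock and stress genes 12 rose and 1 fell in SETDB1 GKD, 13 rose in wde GKD, and 15 rose and 1 fell in Nup154 GKD (12 and 2, 13 and 1, and 15 and 1 adjusted over the list alone). Their medians were 2.56, 2.66 and 2.29, or 2.19, 1.88 and 2.29 with sets at 0 counts at their bound, and 3.46 in Nup154 GKD without NGVP16 control 1 (adjusted p = 1.98e-05, 3.03e-05 and 6.81e-06, and adjusted p = 0.153, 0.0748 and 0.104 with an estimated correlation). Hsp67Bc, a small heat shock gene, rose by 5.03 ± 0.47 in SETDB1 GKD. Hsp70Bb, whose near-identical copies make its counts uncertain, was at 81.7 CPM ± 19.0, 53 ± 28.6 and 141 ± 7 in SETDB1, wde and Nup154 GKD and at 120 ± 51.8 in the virgin pair, against 0.501 ± 0.708 in the NGVP16 pair. Xrp1, a stress transcription factor, rose by 2.28 ± 0.40, 2.74 ± 0.41 and 2.43 ± 0.40, and the checkpoint kinase gene lok fell by 1.61 ± 0.27, 2.28 ± 0.28 and 2.04 ± 0.28. Of 19 cell death and p53 target genes 4 rose and 2 fell, 5 rose and 5 fell, and 6 rose and 3 fell (5 and 3, 6 and 6, and 6 and 3 adjusted over the list alone), with medians of 0.65, 0.12 and 0.20 (adjusted p = 0.223, 0.93 and 0.585).

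Of 5 Hox genes 3 rose in SETDB1 GKD, 4 in wde GKD and 2 in Nup154 GKD (4, 4 and 3 adjusted over the list alone), with medians of 3.01, 3.05 and 2.15 (adjusted p = 0.0036, 0.0146 and 0.0759). With an estimated correlation the first 2 calls ended (adjusted p = 0.317 and 0.481, the highest of ranges from 0.0014 and 0.00349), the wde GKD call also ended with ribosomal protein scaling (adjusted p = 0.0907), and the median was 4.6 in SETDB1 GKD without NGVP16 control 2. In the same libraries the muscle sheath medians were 2.56, 2.42 and 2.44 and the hemocyte medians 2.74, 3.48 and 2.49. The abdominal gene abd-A rose by 3.40 ± 0.52, 3.38 ± 0.52 and 3.90 ± 0.53. Of 19 Polycomb group genes 1 rose, 5 fell, and 1 rose and 2 fell in the 3 knockdowns (0, 3 lower and 2 lower adjusted over the list alone), with medians of -0.29, -0.66 and -0.38 (adjusted p = 0.362, 0.0336 and 0.516). The wde GKD call ended with an estimated correlation (adjusted p = 0.632) and without NGVP16 control 2 (0.484, median -0.31, range over the settings 0.000291 to 0.632). With ribosomal protein scaling the medians were 0.05 in SETDB1 GKD and 0 in wde GKD. Of 12 ecdysone response genes 3 rose, 3 rose, and 3 rose and 1 fell (3, 3, and 3 and 1 adjusted over the list alone), with medians of 0.04, 0.43 and 0.02 (adjusted p = 0.628, 0.402 and 0.588), and the hydroxylase gene Cyp18a1 rose by 1.89 ± 0.32 in wde GKD and 2.57 ± 0.33 in Nup154 GKD.

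Of 27 antimicrobial and immune genes 0 rose in SETDB1 GKD by edgeR, 2 in wde GKD and 3 in Nup154 GKD (0, 0 and 2 adjusted over the list alone), with medians of 0.24, 2.47 and 1.43 (adjusted p = 0.923, 0.0135 and 0.14). The wde GKD call ended with an estimated correlation (adjusted p = 0.665), without wde GKD 1 (0.625, median 0.40), without NGVP16 control 2 (0.267, range over the settings 2.49e-05 to 0.665) and with ribosomal protein scaling (0.0675). Def, a defensin, rose by 5.44 ± 0.90 in Nup154 GKD. Of 20 gut genes 0 rose in SETDB1 GKD, 2 in wde GKD and 0 in Nup154 GKD (0, 0 and 0 adjusted over the list alone), with medians of 5.07, 3.39 and 0.79, or 4.76, 3.25 and 0.79 with sets at 0 counts at their bound (adjusted p = 0.111, 0.0694 and 0.754). Of 16 fat body genes in SETDB1 GKD 1 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.87, or 0.81 at the bound, adjusted p = 0.468). The only Y-linked gene tested, FDY, was at -1.58 (adjusted p = 0.34), -1.75 (0.256) and -0.95 (0.539).

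Several of the largest rises in SETDB1 GKD, such as RpL22-like, were second copies of housekeeping genes, so the class of duplicate copies of translation, respiration and proteasome genes was tested in SETDB1 GKD. A rise of the class was not detected, with a median of 0.83 against 0.019 for all genes: of 26 further copies tested 4 rose (15.4%, against 12.7% of all genes) and 3 fell (camera p = 0.305, and p = 0.557 with an estimated correlation). The 4 that rose included RpS10a (3.87), Cyt-c1L (2.99) and eIF4E6 (2.50), and the 3 that fell were RpS5b (-2.41), RpS14b (-1.53) and RpLP0-like (-1.52).

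Dcr-2 was at 5336 CPM ± 794 in the virgin pair, 813 ± 50.3 in SETDB1 GKD, 220 ± 35.6 in wde GKD, 414 ± 10 in Nup154 GKD and 128 ± 102 in the NGVP16 pair.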
